A study of Rattus norvegicus with 12 samples.

How the data were processed

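Iliopsoas muscle, a hip flexor, was taken from 12 male Wistar rats 9 weeks of age that formed 4 groups of 3 animals. Per the labels' protocols, every rat was anaesthetised, and 30 minutes later the cooled animals were moved to an ambient temperature of 4 °C. Mild, moderate and severe hypothermia were defined by rectal temperatures of 30, 22 and 12 °C at death, and control animals were killed 30 minutes after anaesthesia without cooling. The control temperature of 37 °C was read from the control samples' descriptions. Cooler animals had also spent longer in the cold, so temperature and time could not be separated. Tissue was kept in RNAlater, and stranded poly(A) libraries were made from 2000 ng of total RNA with a TruSeq kit and sequenced on a MiSeq instrument, per the labels' protocols.

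The deposited table gives RPKM (reads scaled by gene length and by the mapped total of the library) for 36865 genes, with 1 column per library. Build rn6 was named per the submitters' processing notes, and the aligner, the counting tool and the annotation were not given in the sources used here. Of these genes, 13456 had a value above 0 in at least 1 library. The 37 mitochondrial genes were listed at 0 in each library, and so was Hspa1a, a near-identical neighbour of Hspa1b, so values of Hspa1b are uncertain. Gene symbols that a spreadsheet had turned into dates (27 genes) were restored through their Entrez identifiers, 28157 of which matched the rat RefSeq table.

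RPKM values are not counts, so no count model was fitted. The 1-read steps of short genes with few libraries above 0 (span under 3000 bases, at most 6 libraries) gave an estimate of the mapped reads behind each library. The implied depths were 2.46, 2.89 and 2.58 M reads for controls 1 to 3 and 2.55, 2.27 and 2.59 M for mild 1, 4 and 5. They were 2.64, 2.53 and 2.11 M for moderate 1 to 3 and 2.48, 2.64 and 3.01 M for severe 1 to 3. In 12 simulated libraries the method returned the total within 0.005 M reads in 12 of 12. The search covered a fixed window of totals that held all simulated ones, so a total outside the window could not have been returned.

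Values were transformed as log2(RPKM + 1), and 9854 genes with a mean of at least 1 RPKM over the 12 libraries were tested with limma 3.58.1 in R 4.3.3. Fold changes are on this scale, which understates the change of genes with low RPKM. A linear model with 4 group means (8 residual degrees of freedom, 3.39 prior) gave each stage against control, each pair of stages and a test for any difference. A second model gave the slope per 10 °C of cooling over 37, 30, 22 and 12 °C. Moderated tests used an intensity trend, two-sided p-values and the Benjamini-Hochberg adjustment over all genes, with a threshold of 0.05. With 3 animals against 3, an exact permutation test could not go below 0.1.

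31 gene lists were fixed for stress responses, muscle metabolism, fibre types and other cell types in dissected muscle. 29 of them had at least 3 tested members, while the neutrophil and monocyte list and the lymphocyte list had 2 each and were not tested. Lists were tested with camera, which compares a list with all other genes, at a preset inter-gene correlation of 0.01, then with an estimated correlation and with fry, adjusted over the lists of each comparison. Member genes were also counted after the p-values were adjusted over the list alone. Per animal, a list was scored by the mean of its log2 values, and slopes of scores were tested by 100000 two-sided permutations of the temperatures.

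The model, the filter, the lists, the alternatives and the rule for naming genes were set before the data were examined. For each stage against control and for the trend, the rule took up to 8 rises and 8 falls past the threshold, with no placeholder symbol and no overlap with control libraries, or the 5 smallest p-values where fewer than 3 genes passed. It added 14 genes named in every comparison, and between stages the 4 largest rises and falls past the threshold. Other genes named as examples of a list were chosen after their values were seen. Alternatives covered the pseudocount, the filter, rescaling, array weights, the threshold, a replicate block, group rank in place of degrees and the omission of each library. Covariates for fibre type and fat, the omission of 3 libraries low in myoglobin, the omission of microRNA genes and the simulated correlations with fewer libraries were chosen after seeing the data.

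The gene test was tested on simulated data with the real means and spreads, in which 200 of 9854 genes were changed. A log2 change of 1 was recovered in 61.5% of changed genes for mild, 65% for moderate and 61.5% for severe against control, and in 69.5% for a trend reaching 1 at 12 °C. A log2 change of 2 was recovered in 89%, 91.5%, 93% and 96% of them. A list shifted by 1 in the severe group was called in both camera modes, with 0 other lists called. The simulated genes were independent and each had 1 spread over all groups, so the recovered shares may not hold for these libraries. Nor could this show how often camera calls lists whose members vary together. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 read the table and drew the plots.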

Results

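Transcripts of rat iliopsoas muscle were measured in 3 control animals and in 3 animals each at rectal temperatures of 30 °C (mild), 22 °C (moderate) and 12 °C (severe hypothermia). The series asks which transcripts follow body temperature and could mark death from cold. Each library came from its own animal. Implied depth lay between 2.11 M reads (moderate 3) and 3.01 M reads (severe 3), and rank correlations between libraries of the same group were 0.924 to 0.98 across genes. The first principal component held 36.1% of the variance and set moderate 1, moderate 3 and severe 3 (26.9, 29.2 and 50.1) apart from the other libraries (-25 to 2.9). Genes of slow fibres marked one end of it and fat genes the other. Mb, the oxygen-binding myoglobin of oxidative fibres, read 1430, 459 and 1380 RPKM in those libraries against 5810 ± 580 RPKM in controls (mean ± SD, n = 3). Values below are mean ± SD RPKM with n = 3 animals per group, and changes are log2 differences with their standard errors (SE).

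Cooling to 30 °C was compared with control to ask what an early drop in body temperature does. Fast-twitch fibre genes stood higher than other genes as a group, with 14 of 14 tested members above control (adjusted p = 3.43e-06, and adjusted p = 0.73 with an estimated correlation). Among them were Atp2a1 (0.29, SE 0.12), the calcium pump of fast fibres, and Myh4 (0.33, SE 0.23), a fast myosin heavy chain. Fibroblast and matrix markers fell as a group, with 13 of 13 members below control (mean -0.63, adjusted p = 0.00539, and adjusted p = 0.88 with an estimated correlation), including the collagen-binding proteoglycans Lum (-0.57, SE 0.23) and Dcn (-0.54, SE 0.26). The score of this list was 5.25 in mild 1, within the controls (4.98, 5.00 and 5.38), and 4.01 and 4.20 in mild 4 and mild 5. On the 3rd principal component (8.41% of variance) mild 4 and mild 5 lay at -20.5 and -12.8 and mild 1 at 12.3, with the tendon genes Kera, Tnmd, Fmod, Thbs4 and Chad among the strongest at the positive end. Ucp3, Angptl4, Pdk4 and Fbxo32 were among the strongest at its negative end. Fatty acid uptake and oxidation genes scored 5.63 in mild 1 and 6.79 and 6.85 in mild 4 and mild 5, against 6.35 to 6.65 in controls. Erythroid markers (mean 0.47, 6 of 7 higher, adjusted p = 0.00849), glycolysis and glycogen genes (mean 0.02, 15 of 22 higher, 0.0104) and smooth muscle and pericyte markers (mean 0.08, 9 of 13 higher, 0.0253) also stood higher than other genes, each with an adjusted p of 0.73 with an estimated correlation. Pon3, a paraoxonase, had the smallest p of any gene without a placeholder symbol, at 7.69 ± 2.48 RPKM against 16.7 ± 4.22 (-1.04, SE 0.22, adjusted p = 0.88).

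The other 4 genes with the smallest p-values were Abcb9, a lysosomal peptide transporter (-0.61), Snx10, a sorting nexin (-1.26), Rtel1, a DNA helicase (-0.74), and Micu2, a gatekeeper of mitochondrial calcium uptake (-0.40). Each had an adjusted p of 0.88. Among cold-inducible RNA-binding proteins, Cirbp measured 7.9 ± 1.42 RPKM against 8.09 ± 1.36 in controls (-0.03) and Rbm3 20.8 ± 4.17 against 17.0 ± 0.898 (0.26). The immediate early transcription factors Fos (-0.37), Jun (-0.05), Egr1 (-0.75), Atf3 (-1.05) and Nr4a1 (-0.58) had log2 means below control. So did Pdk4, which restrains glucose oxidation (-0.59), the uncoupling protein Ucp3 (-0.33), the calcium pump regulator Sln (-1.58) and the clock gene Per1 (-0.76), although mean RPKM of Pdk4 (326 against 294) and Ucp3 (101 against 71.5) lay above it. The chaperone Hspa1b (-0.19), the cell cycle inhibitor Cdkn1a (-1.40) and the myogenic factor Myod1 (-0.47) also had log2 means below control, and none of these 14 fixed genes passed the test (adjusted p from 0.91 to 1). Immediate early genes as a list averaged -0.50 with 31 of 32 members lower (adjusted p = 0.412), and glucocorticoid-responsive genes averaged -0.38 with 22 of 27 lower (adjusted p = 0.17).

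By limma, 0 of 9854 genes passed an adjusted p of 0.05 in mild hypothermia, and 544 had an unadjusted p under 0.05 (42 higher, 502 lower) where chance gives 493. All-gene medians lay at -0.10 in each stage against control. Rescaling by the median of ratios took this shift out and split the genes under an unadjusted p of 0.05 into 123 higher and 146 lower in mild, 448 and 513 in moderate, and 541 and 453 in severe hypothermia. As deposited, mild and control libraries did not overlap for 1418 genes (14.4%, where chance gives 10%). Size factors of the median-of-ratios rescaling were 1.04 to 1.11 in controls and 0.958 to 0.998 in mild libraries. The shift can therefore separate the groups by itself, and overlap was not counted after rescaling for any stage. 5 of 29 lists passed by camera, 4 higher and 1 lower. In these lists 0 members passed, both over all genes and adjusted over the list alone. Arrdc2 (-1.29, SE 0.32), an arrestin family gene, passed within the glucocorticoid list when limma p-values were adjusted over the list alone (adjusted p = 0.046). Fast-twitch genes turned direction under quantile normalization (adjusted p = 0.57), which also ended the calls of glycolysis (0.99), erythroid (0.14) and smooth muscle genes (0.05). Lists called under quantile normalization were 0 higher and 4 lower, 1 of them called as deposited, and after the median of ratios 5 were higher and 3 lower. Rescaling by the median of ratios gave erythroid markers 0.056, and with no filter glycolysis and smooth muscle genes had 0.11 each. The number of lists was 10 without control 1 or mild 1 and 3 without control 2, mild 4 or mild 5, and 1 gene passed without moderate 3. Fibroblast markers lost their call without control 3 (0.077), mild 4 (0.25) or mild 5 (0.14), erythroid markers without control 2 (0.071) or mild 5 (0.50), glycolysis without control 2 (0.085) or mild 4 (0.063), and smooth muscle markers without control 3 (0.15), mild 4 (0.38) or mild 5 (0.073).

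Cooling to 22 °C was compared with control in the same way. Glucocorticoid-responsive genes rose as a group (mean 0.66, 24 of 27 higher, adjusted p = 9.94e-09, and adjusted p = 0.21 with an estimated correlation), with Sesn1, a stress-inducible regulator of growth signalling, at 0.99 (SE 0.26). Muscle atrophy and autophagy genes also rose (mean 0.50, 14 of 20 higher, adjusted p = 4.57e-06, and adjusted p = 0.21 with an estimated correlation), with the ubiquitin ligases Fbxo32 at 1.51 (SE 0.45) and Trim63 at 0.83 (SE 0.33). Immediate early genes rose by a mean of 0.45 (23 of 32 higher, adjusted p = 2.01e-05, and adjusted p = 0.41 with an estimated correlation). Their score was 3.55, 5.52 and 3.04 in moderate 1 to 3 against 3.21 to 3.90 in controls, so only moderate 2 lay above the controls. Slow-twitch fibre genes fell as a group (mean -3.23, 14 of 15 lower, adjusted p = 2.01e-05, and adjusted p = 0.30 with an estimated correlation), with the slow myosin Myh7 at 0 to 121 RPKM against 311 ± 109. Adipocyte markers rose (mean 2.04, 10 of 11 higher, adjusted p = 1.52e-06, and adjusted p = 0.30 with an estimated correlation), with the fat hormone Adipoq at 3.71 (SE 1.55). Moderate 1 and moderate 3 were the libraries low in Mb (1430 and 459 RPKM).

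Heat shock chaperones fell as a group (mean -0.41, 15 of 16 lower, adjusted p = 0.000154, and adjusted p = 0.21 with an estimated correlation), with Hspa1l (-0.95, SE 0.25), Dnaja1 (-0.51, SE 0.15) and Dnajb1 (-0.73, SE 0.23). Endothelial markers fell (mean -0.39, 13 of 14 lower, adjusted p = 0.00134, and adjusted p = 0.29 with an estimated correlation), including the junction proteins Pecam1 (-0.54, SE 0.15) and Cdh5 (-0.53, SE 0.15). The score of this list was 3.32 and 3.40 in moderate 1 and moderate 3, the libraries low in Mb, and 3.81 in moderate 2, within the controls (3.79 to 4.10). Nuclear-encoded genes of oxidative phosphorylation fell, with 36 of 36 lower (mean -0.42, adjusted p = 7.21e-08, and adjusted p = 0.41 with an estimated correlation), and their score was 8.36, 8.81 and 8.48 in moderate 1 to 3 against 8.87 to 9.05 in controls. Fatty acid uptake and oxidation genes fell, with 19 of 22 lower (mean -0.37, adjusted p = 0.0083, and adjusted p = 0.46 with an estimated correlation). Fast-twitch genes stood higher in 12 of 14 cases (mean 0.13, adjusted p = 1.68e-08, and adjusted p = 0.21 with an estimated correlation), led by Myh4 at 8570 ± 2100 RPKM against 4990 ± 810. In glycolysis and glycogen (mean 0.11, 15 of 22 higher, adjusted p = 0.00139, and adjusted p = 0.29 with an estimated correlation) Pfkfb3, which stimulates glycolysis, read 213 ± 47.1 RPKM against 48.1 ± 23.4, and Gys1, the glycogen synthase of muscle, 112 ± 11.3 against 159 ± 14.9.

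Among genes without a placeholder symbol, the 5 smallest p-values belonged to Sox18, a transcription factor of blood and lymph vessels (-1.93, SE 0.27, adjusted p = 0.069), the chemokine receptor Cxcr4 (-1.28), the inositol phosphatase Impa2 (-1.46), the peroxidase Prdx1 (-0.49) and Sat1, which degrades polyamines (1.52), the last 4 at an adjusted p of 0.26. Sox18 read 4.41 ± 1.6 RPKM against 19.1 ± 2.6 and Sat1 55.8 ± 16 against 18.4 ± 3.19. Of the fixed genes, Rbm3 stood at 34.2 ± 7.87 RPKM (0.95, SE 0.24, adjusted p = 0.26), Cirbp at 10.9 ± 1.44 (0.40), Myod1 at 5.49 ± 1.78 (-1.97, SE 0.47, adjusted p = 0.26) and Hspa1b at 6.98 ± 1.69 (-1.20, SE 0.35, adjusted p = 0.27). Differences for the others were Fos 1.28, Jun 0.03, Egr1 2.09, Atf3 -0.09, Nr4a1 0.05, Pdk4 1.07, Ucp3 1.32, Sln -0.01, Per1 0.57 and Cdkn1a 0.78, with adjusted p from 0.43 to 1. Fos ranged from 2.52 RPKM in moderate 3 to 205 RPKM in moderate 2.

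By limma, 0 genes passed in moderate hypothermia and 1305 had an unadjusted p under 0.05 (171 higher, 1134 lower). As deposited, libraries did not overlap for 2256 genes (22.9%, chance 10%), a share open to the same shift (size factors 0.968 to 1.01 in moderate libraries). Camera called 21 of 29 lists, 16 higher and 5 lower. Besides the lists above, those called higher were fibroblast and matrix markers (mean 0.46, adjusted p = 9.47e-05), p53 and cell cycle genes (0.28, 0.000472), macrophage markers (0.26, 0.00193), inflammatory genes (0.20, 0.0112), the unfolded protein response (0.18, 0.0147), cholesterol synthesis (0.47, 0.0157), erythroid markers (0.38, 0.0166), clock genes (0.11, 0.0219), hypoxia genes (0.11, 0.0404) and muscle thermogenesis genes (-0.09, 0.0424). With an estimated correlation their adjusted p was 0.30, 0.21, 0.46, 0.30, 0.26, 0.41, 0.30, 0.21, 0.21 and 0.21. Hypoxia genes had a median of -0.04 against a mean of 0.11, and thermogenesis genes a median of 0.01 against a mean of -0.09, although both were tested as higher than other genes.

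Over all genes 0 list members passed in moderate hypothermia. Adjusted over the list alone, 1 slow-twitch gene (Fhl2) was higher and 12 lower, 8 heat shock genes and 4 endothelial genes were lower, and 6 fast-twitch genes were higher and 2 lower. Without moderate 2, adjusted p was 0.98 for immediate early genes, 0.30 for clock genes, 0.22 for hypoxia genes, 0.12 for the unfolded protein response, 0.11 for inflammatory genes, 0.083 for erythroid markers and 0.07 for cholesterol synthesis. Without moderate 3, macrophage markers had 0.92 and fatty acid genes 0.058, and without moderate 1 fatty acid genes had 0.14. Without control 3, erythroid markers had 0.07, hypoxia genes 0.087, inflammatory genes 0.078, macrophage markers 0.053 and the unfolded protein response 0.066, while cholesterol synthesis (0.076) and erythroid markers (0.055) lost their calls without control 2 and clock genes (0.051) without control 1. Omitting the 3 libraries low in Mb leaves moderate 2 as the only moderate animal, with the spread taken from the other groups, so that omission is not read for this stage. Lists numbered 16 after rescaling by the median of ratios and 14 after quantile normalization, which ended the fast-twitch and glycolysis calls (0.31 each). Under both rescalings hypoxia, clock, inflammatory, cholesterol and erythroid genes lost their calls (0.081 to 0.12), and with no filter hypoxia (0.12), clock (0.06), inflammatory and cholesterol genes (0.052 each) did. Thermogenesis genes turned direction under quantile normalization (0.80), had 0.10 after the median of ratios and 0.15 with no filter, and lost their call without control 2 or 3, moderate 1, 2 or 3, or severe 1 or 3 (0.057 to 0.10). Without severe 3, which enters the shared spread, 19 genes passed (12 higher, 7 lower), Sox18 (adjusted p = 0.022) among them.

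Cooling to 12 °C was compared with control to ask what the lowest temperature does. Immediate early genes rose as a group (mean 1.54, 29 of 32 higher, adjusted p = 1.01e-19, and adjusted p = 0.18 with an estimated correlation), with Fos at 189 ± 128 RPKM against 14.2 ± 12.9 in controls (3.87, SE 1.25) and Egr1 at 412 ± 422 against 17.4 ± 6.69 (3.95, SE 1.11). Glucocorticoid-responsive genes rose (mean 1.12, 26 of 27 higher, adjusted p = 1.71e-20, and adjusted p = 0.079 with an estimated correlation), with the receptor chaperone Fkbp5 (0.92, SE 0.22) and the transcription factors Foxo3 (1.31, SE 0.31) and Klf9 (0.84, SE 0.21). Muscle atrophy and autophagy genes rose (mean 0.74, 17 of 20 higher, adjusted p = 4.33e-11, and adjusted p = 0.11 with an estimated correlation), with Trim63 at 683 ± 253 RPKM against 270 ± 8.57 and the autophagosome protein Gabarapl1 at 206 ± 94.7 against 78.6 ± 20.7. Inflammatory genes (mean 0.56, 14 of 18 higher, adjusted p = 2.82e-05) and p53 and cell cycle genes (mean 0.50, 13 of 19 higher, adjusted p = 5.35e-05) also rose, with an adjusted p of 0.15 and 0.079 with an estimated correlation. The cytokine receptor Osmr stood at 0.76 (SE 0.20) and the stress kinase Plk2 at 1.01 (SE 0.24).

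**Figure D1:**
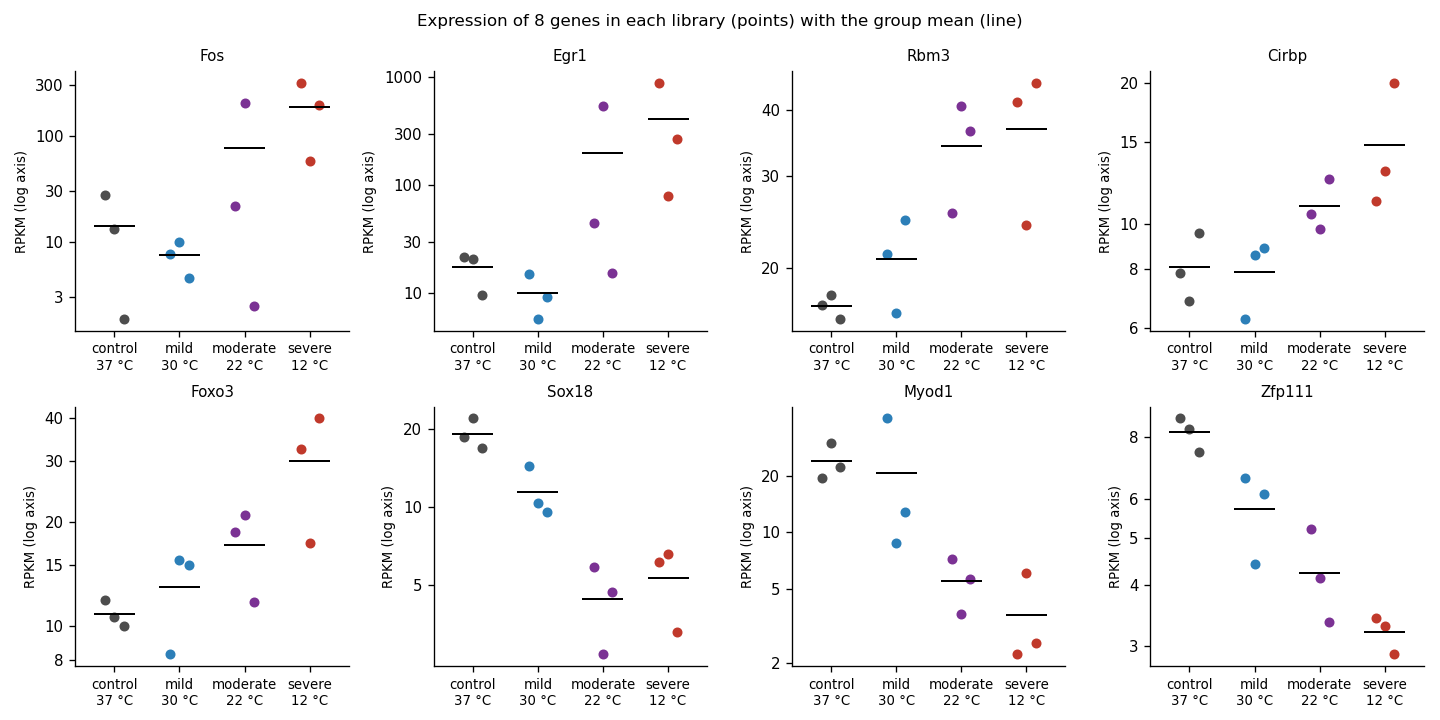
RPKM on a log axis of 8 genes in each library (points) by group, with the arithmetic group mean as a line and n = 3 animals per group. Zfp111 lay between 2.89 and 3.43 RPKM in severe hypothermia and between 7.48 and 8.75 RPKM in controls, while Fos spread from 57.8 to 314 RPKM in severe and from 1.88 to 27.6 RPKM in control animals.

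The 5 smallest p-values against control belonged to Mir3582, a row named for a microRNA (-3.36, SE 0.46), the zinc finger gene Zfp111 (-1.13, SE 0.17), Sox18 (-1.71, SE 0.27), the growth regulator Ing4 (-0.68, SE 0.12) and the vasodilator peptide Adm (1.92, SE 0.33), each at an adjusted p of 0.11. Adm read 14.1 ± 4.95 RPKM against 2.93 ± 0.847. Rbm3 stood at 36.9 ± 11.1 RPKM (1.03, SE 0.24, adjusted p = 0.20), Cirbp at 14.7 ± 4.67 (0.76, SE 0.21, adjusted p = 0.21) and Myod1 at 3.6 ± 2.11 against 24.1 ± 5.39 (-2.52, SE 0.47, adjusted p = 0.16). Differences for the other fixed genes were Jun 0.50, Atf3 2.56, Nr4a1 1.59, Pdk4 1.38, Ucp3 1.16, Sln 0.21, Per1 1.46, Hspa1b -0.19 and Cdkn1a 1.04, with adjusted p from 0.35 to 0.95. In the cold-inducible list (adjusted p = 0.133) 3 genes including Rbm3 and Cirbp passed as higher and 2 including the splicing kinase Clk1 (-0.88) as lower when adjusted over the list alone, and 0 passed over all genes.

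By limma, 0 genes passed in severe hypothermia and 1232 had an unadjusted p under 0.05 (291 higher, 941 lower). As deposited, libraries did not overlap for 1808 genes (18.3%, chance 10%), a share open to the same shift (size factors 0.971 to 1.01 in severe libraries). Camera called 13 of 29 lists, 12 higher and 1 lower. Adjusted over the list alone, 15 glucocorticoid-responsive genes were higher, 13 immediate early genes were higher and Ier3 was lower, and 5 atrophy genes were higher, while over all genes 0 members passed. Adipocyte markers (6.77e-05, mean 1.38), cholesterol synthesis (0.000701, mean 0.56), erythroid markers (0.00196, mean 0.89), hypoxia genes (0.00235, mean 0.31), clock genes (0.00331, mean 0.41), the unfolded protein response (0.00599, mean 0.26) and fibroblast and matrix markers (0.0256, mean 0.18) were called higher, and oxidative phosphorylation (0.00104, mean -0.28) lower. With an estimated correlation these had adjusted p of 0.44, 0.34, 0.24, 0.079, 0.11, 0.18, 0.61 and 0.62.

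Single libraries decided several of these values. Severe 3, low in Mb, held Adipoq at up to 617 RPKM where the lowest severe library had 1.22. Without severe 3, adipocyte markers (adjusted p = 0.69) and oxidative phosphorylation (0.45) turned direction, and cholesterol synthesis (0.45) and fibroblast markers (0.69) lost their calls. Fibroblast markers also lost theirs without control 1 (0.054) or control 2 (0.11), with no filter (0.06) and after rescaling by the median of ratios (0.093) or quantiles (0.089). Without severe 2, 136 genes passed against control (56 higher, 80 lower), while 2 passed without mild 1 and 1 without moderate 3 or severe 1. Slow-twitch genes (mean -1.52, adjusted p = 0.241) and heat shock chaperones (mean -0.16, adjusted p = 0.0938) did not pass at this stage, and Myh7 ranged from 0.0841 to 489 RPKM.

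**Figure D2:**
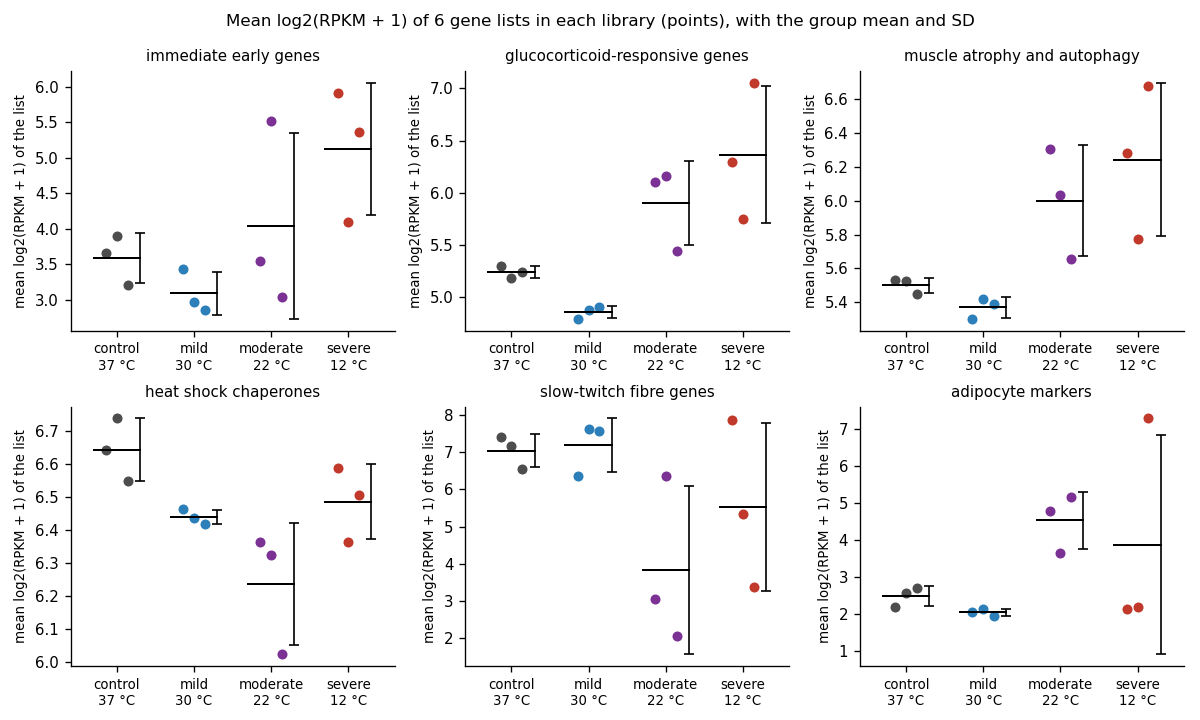
Mean log2(RPKM + 1) of 6 gene lists in each library (points) by group, with the group mean as a line, the SD as an error bar and n = 3 animals per group. The slow-twitch score was 3.049 and 2.04 in moderate 1 and moderate 3 and 3.36 in severe 3, and the adipocyte score was 7.282 in severe 3 against 2.15 and 2.184 in severe 1 and severe 2.

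Stages were compared with each other to test differences directly. LOC303448, a locus described as similar to the glycolytic enzyme gene Gapdh (chromosome 10, 78687656 to 78696097, rn6), was lower in severe than in moderate hypothermia by limma (-1.11, SE 0.13, adjusted p = 0.026). It measured 5.13 ± 0.306, 8.35 ± 0.997, 11.6 ± 1.05 and 4.8 ± 0.429 RPKM from control to severe. This was the 1 gene passing between severe and moderate (560 at an unadjusted p under 0.05). It was the only call there without mild 5, was 1 of 9 calls without severe 3, and had adjusted p of 0.055 to 0.26 without any of the other 10 libraries. By limma, 0 genes passed between moderate and mild (1225 at an unadjusted p under 0.05) or between severe and mild (1137). Without severe 1, severe 2 or severe 3, 3, 1 and 33 genes passed between moderate and mild, and 2, 1 and 180 passed between severe and mild without moderate 3, severe 1 and severe 2. Camera called 17 lists between moderate and mild, 15 between severe and mild and 15 between severe and moderate, and 0 in each with an estimated correlation. Severe animals stood above moderate ones in immediate early genes (mean 1.09, 32 of 32 higher, camera adjusted p = 6.94e-09), endothelial markers (0.43, 8.98e-07) and slow-twitch genes (1.70, 8.15e-05) and below them in fast-twitch genes (-0.14, 1.06e-05), each with an adjusted p of 0.43 with an estimated correlation. The slow-twitch score was 3.05, 6.37 and 2.04 in moderate 1 to 3 and 7.86, 5.35 and 3.36 in severe 1 to 3. The test for any difference among the 4 groups passed 0 genes (1193 at an unadjusted p under 0.05) by limma, and 2, 4, 51 and 13 without moderate 3, severe 1, severe 2 and severe 3.

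The trend over all 12 animals asks which transcripts follow body temperature. As deposited, 3 genes fell with cooling, each past an adjusted p of 0.05, and 0 rose. After rescaling by the median of ratios the same 3 fell and 4 rose, so the lack of rising genes depends on the scaling. Mir3582 (chromosome 18, 2052459 to 2052576) fell from 18.5 ± 8.04 RPKM in controls to 0.999 ± 1.2 in severe animals (slope -1.37 per 10 °C, SE 0.17, adjusted p = 0.016). At the implied depths, that severe mean and SD do not match whole reads on so short a span. What the Mir3582 row measures is therefore uncertain. Rab23, a small GTPase of vesicle traffic (chromosome 9, 38471716 to 38495126), fell from 6.17 ± 0.626 to 2.05 ± 0.451 RPKM (-0.50, SE 0.08, adjusted p = 0.048). Zfp111 (chromosome 1, 81035711 to 81046934) fell from 8.19 ± 0.652 through 5.73 ± 1.16 and 4.23 ± 0.924 to 3.21 ± 0.282 RPKM (-0.44, SE 0.07, adjusted p = 0.048).

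Myod1 came next among the fixed genes (-1.08, SE 0.18, adjusted p = 0.051), then Rbm3 (0.45, SE 0.09, 0.077), Cirbp (0.33, SE 0.08, 0.098) and Egr1 (1.81, SE 0.45, 0.098), none of them past the adjusted threshold. Slopes of the others were Fos 1.65, Jun 0.20, Atf3 1.11, Nr4a1 0.69, Pdk4 0.71, Ucp3 0.61, Sln 0.30, Per1 0.71, Hspa1b -0.16 and Cdkn1a 0.66, with adjusted p from 0.14 to 0.78. In all, 1536 genes had an unadjusted p under 0.05 (429 higher, 1107 lower), which became 726 higher and 622 lower after rescaling by the median of ratios. The count of 3 was 221 (61 higher, 160 lower) without severe 2, 4 without mild 4, 2 without mild 1, and 1 without control 2, mild 5, moderate 1, moderate 2 or severe 1. It was 0 without control 1, control 3 or severe 3, without the 3 libraries low in Mb, and with the adipocyte score as a covariate. It was 2 at pseudocounts of 0.1 and 0.5, where Rab23 had an adjusted p of 0.053 and 0.05, and with the slow-twitch score as a covariate, where Zfp111 had 0.10. Slopes of Mir3582, Rab23 and Zfp111 were -1.25, -0.57 and -0.43 without the libraries low in Mb and -1.27, -0.55 and -0.42 with the adipocyte covariate, so the calls ended while the slopes stayed close to -1.37, -0.50 and -0.44.

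Among lists, glucocorticoid-responsive genes rose with cooling by 0.54 per 10 °C on average (26 of 27 higher), immediate early genes by 0.70 (30 of 32 higher) and atrophy and autophagy genes by 0.35 (17 of 20 higher). Camera gave adjusted p of 1.48e-20, 2.3e-19 and 2.18e-11, and with an estimated correlation the adjusted p was 0.11, 0.18 and 0.11. Examples are the transcription factors Junb (1.33, SE 0.28) and Myc (0.83, SE 0.17), Foxo3 (0.53, SE 0.11), Trim63 (0.62, SE 0.15) and Klf9 (0.41, SE 0.10). Adjusted over the list alone, 17 glucocorticoid-responsive, 21 immediate early and 8 atrophy genes were higher and 1 immediate early gene (Ier3) lower, while over all genes 0 passed. Of these 3 lists, 14, 3 and 8 tested members respectively also belonged to another list.

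Camera called 16 of 29 lists in the trend, 14 higher and 2 lower. The others called higher were adipocyte markers (mean 0.78, adjusted p = 1.01e-05), inflammatory cytokines and NF-kB targets (0.28, 1.17e-05), p53 and cell cycle genes (0.26, 1.35e-05), fibroblast and matrix markers (0.20, 0.00053), cholesterol and lipid synthesis (0.27, 0.000722), clock genes (0.19, 0.00334), hypoxia genes (0.14, 0.00349), the unfolded protein response (0.14, 0.0038), erythroid markers (0.31, 0.00439), macrophage markers (0.11, 0.0125) and nerve and Schwann cell markers (0.16, 0.0477). Oxidative phosphorylation (mean -0.14, 36 of 36 lower, 5.81e-06) and slow-twitch genes (mean -0.90, 14 of 15 lower, 0.0399) were called lower. With an estimated correlation the adjusted p of these 13 lists was 0.31, 0.17, 0.11, 0.49, 0.31, 0.11, 0.11, 0.22, 0.29, 0.62, 0.22, 0.62 and 0.62. Without the 3 libraries low in Mb, macrophage markers (0.96) turned direction and oxidative phosphorylation (0.96), slow-twitch genes (0.42), adipocyte markers (0.34), cholesterol synthesis (0.27), nerve markers (0.22) and fibroblast markers (0.13) lost their calls. Mb is itself a member of the slow-twitch list, so omitting libraries chosen for low Mb says little about the slow-twitch call. Removal of severe 3 ended the calls of oxidative phosphorylation (0.052), cholesterol synthesis (0.059), macrophage markers (0.11), slow-twitch genes (0.18) and nerve markers (0.12). The slow-twitch call also ended without control 1, mild 1, 4 or 5, moderate 1 or severe 2 (0.051 to 0.13) and at a pseudocount of 0.1 (0.051), the nerve call without control 2 or 3, mild 1 or 5, or moderate 1 or 2 (0.051 to 0.11), with no filter (0.16), at a pseudocount of 0.1 (0.053) and under both rescalings (0.11 and 0.068), the macrophage call without control 3 (0.064) or after the median of ratios (0.078) and the erythroid call without severe 1 (0.054).

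The other 13 lists did not pass in the trend. Mean slopes and adjusted p were 0.20 and 0.063 for oxidative stress and metallothionein genes, -0.07 and 0.082 for heat shock chaperones, -0.01 and 0.114 for fast-twitch genes, 0.04 and 0.124 for cold-inducible genes, 0.04 and 0.167 for glycolysis, and 0.00 and 0.272 for sarcomere and mechanical stress genes. They were 0.02 and 0.428 for muscle thermogenesis, -0.05 and 0.428 for myogenic regulators, -0.02 and 0.699 for smooth muscle markers, -0.02 and 0.765 for cytosolic ribosomal proteins, -0.01 and 0.951 for endothelial markers, -0.04 and 0.951 for ion channels, and 0.00 and 0.951 for fatty acid genes. Mean and median differed in sign for fast-twitch (median 0.03), cold-inducible (-0.01) and myogenic genes (0.01), and fast-twitch, myogenic, endothelial and smooth muscle genes were tested as higher than other genes despite a mean below 0. Control muscle expressed at least 1 RPKM of 14 of 14 endothelial, 13 of 13 fibroblast, 16 of 16 macrophage, 13 of 13 smooth muscle, 8 of 8 nerve, 6 of 7 erythroid and 9 of 11 adipocyte genes tested, and 0 of these belonged to another list. Adjusted over the list alone, 3 cold-inducible genes were higher and 2 lower, 2 oxidative stress genes, 1 glycolysis gene and the endothelial junction gene Cldn5 (0.76, SE 0.13) were higher, and Dnaja1 (-0.25) and Myod1 were lower. In the sarcomere list Trim63 was higher and Amd1 lower. Over all genes 0 of these passed.

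Fold changes of the stages were compared across the 9854 genes, which are not independent replicates. Moderate and severe changes correlated with r = 0.69 (rho = 0.62) and a covariance of 0.105, and 74.6% of genes had the same sign. Unchanged groups simulated against the same controls (100 simulations) gave r = 0.50, a covariance of 0.0362 and 66.6% of genes with the same sign, so the covariance lay 0.069 above the simulated mean. The simulated genes were independent, while real genes vary together, so how widely the covariance would vary by chance is not known. Mild changes correlated with r = 0.10 (rho = 0.16) to moderate and r = 0.16 (rho = 0.19) to severe changes, with covariances of 0.00944 and 0.0152, which lay -0.0267 and -0.021 from the simulated one. The 3 control libraries were not split between the stages. The simulation shared them too, but gave all groups 1 pooled spread per gene. Rank correlations were 0.9745 to 0.9795 between control libraries and 0.924 to 0.9596 between severe ones, so the simulated covariance may be too large. How much of any difference comes from the shared controls is not known, and the mild values below the simulated one are not read as a result. With 0 calls per stage no overlap of called genes could be given. The moderate to severe value was 0.41 without severe 3, below the 0.45 simulated for the same libraries. Its covariance was then 0.0549 against 0.0296 simulated, an excess of 0.0253. Omitting the libraries low in Mb, which leaves moderate 2 as the only moderate animal, gave r = 0.56 against 0.32 simulated. The covariance excess was then 0.0573. The mild to moderate value was -0.03 without mild 1, 0.26 without control 3, 0.18 without mild 4, 0.17 without control 2 and 0.16 without control 1 or mild 5. The mild to severe value was 0.07 without mild 1, 0.09 without severe 2, 0.10 without severe 1, 0.31 without severe 3, 0.26 without control 2 and 0.25 without control 1 or control 3.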

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

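The tests of LOC303448 against Gapdh and among the 4 groups were chosen only after the result was seen.

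LOC303448 differed between stages of cooling, with a log2 difference of -1.11 (SE 0.13) between severe and moderate hypothermia and non-overlapping values in the 2 groups. Its libraries held 10.4, 11.9 and 12.4 RPKM in moderate and 5.24, 4.38 and 4.78 RPKM in severe animals. Because the locus resembles Gapdh, one of the most abundant muscle transcripts, reads shared with Gapdh were weighed: the ratio of the 2 genes would then stay level, yet it differed by -1.04 (SE 0.14) on the log2 scale, while Gapdh itself differed by -0.23 (SE 0.09), which argues against shared reads as the whole cause. An effect of the stage of cooling stays open, because the test for any difference among the 4 groups gave an adjusted p of 0.066 and because the 10 ways to split the 6 libraries are too few for a share under 0.05. The real split called 1 gene and 3 splits called as many; the highest other called 261 genes, when it set moderate 1, moderate 3 and severe 3 against the rest, which points to a structure of the samples.

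Fibroblast and matrix markers were called in opposite directions at different stages, and the difference itself passed by camera, with a mean of 1.09 between moderate and mild (adjusted p = 1.65e-08, and adjusted p = 0.36 with an estimated correlation). The same list differed by 0.81 between severe and mild hypothermia (adjusted p = 8.28e-06, and adjusted p = 0.37 with an estimated correlation). The mild call ended without control 3 (0.077), mild 4 (0.25) or mild 5 (0.14). Between moderate and mild, adipocyte markers also differed, by a mean of 2.48 (11 of 11 higher, adjusted p = 7.04e-05, and adjusted p = 0.37 with an estimated correlation), macrophage markers by 0.66 (16 of 16 higher, 0.000705, and 0.46 with an estimated correlation), smooth muscle markers by -0.31 (13 of 13 lower, 0.00225, and 0.37 with an estimated correlation), endothelial markers by -0.30 (0.000802, and 0.36 with an estimated correlation) and slow-twitch genes by -3.37 (3.15e-08, and 0.36 with an estimated correlation). Between severe and mild, adipocyte markers differed by 1.82 (0.000705, and 0.62 with an estimated correlation), macrophage markers by 0.47 (0.0239, and 0.71 with an estimated correlation) and slow-twitch genes by -1.67 (0.00923, and 0.62 with an estimated correlation).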

How the results depend on the processing

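The covariates for fibre type and fat, the omission of the 3 libraries low in myoglobin and the omission of microRNA genes were tests chosen only after the results were seen.

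With no filter on low values, genes past the threshold numbered 2 for mild, 1 for severe, 1 for moderate against mild, 2 for severe against moderate, 2 for severe against mild, 1 for the trend and 3 for any difference. A filter at 5 RPKM left 1 gene in the trend. Rescaling by the median of ratios gave 1 gene in moderate, 7 in the trend and 8 lists in mild. Those 7 were the 3 reported as lower and 4 higher with cooling: Slc43a1, Adm, Cldn5 and H3f3b (adjusted p = 0.035 each by limma). Quantile normalization gave 1 in moderate and 12 in the trend (6 higher, 6 lower). At an adjusted p of 0.1, 2 genes passed in moderate, 133 in the trend and 2 for any difference. Array weights gave 2 in moderate, 4 in moderate against mild, 0 in severe against moderate, 7 in the trend and 3 for any difference. Only the 2 groups compared gave 1 in mild, group rank in place of degrees gave 7 in the trend, and the 9 cooled libraries without controls gave 0. The slow-twitch covariate gave 1 in moderate, 2 in severe, 1 in moderate against mild, 0 in severe against moderate, 32 in severe against mild and 1 for any difference. The adipocyte covariate gave 0 in severe against moderate and 0 in the trend. Without the 3 libraries low in myoglobin, counts were 2 in mild, 2 in moderate, 0 in severe against moderate, 0 in the trend, 5 for any difference and 8 lists in mild; moderate 2 is then the only moderate animal and the other groups supply its spread, so the counts for moderate and for severe against moderate test a single library. Without the 7 microRNA genes the trend had 0 genes, with an adjusted p of 0.056 for Rab23 and Zfp111. The cause was not tested for the counts that moved. An estimated correlation gave 0, 0, 0 and 0 lists in the mild, moderate, severe and trend families, and so did fry (0 in each). Fry was also run between the stages, and those results are not given here.

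The lists that reversed did so at adjusted p of 0.57 (fast-twitch, mild) and 0.80 (thermogenesis, moderate) under quantile normalization, 0.45 (oxidative phosphorylation, severe) and 0.69 (adipocyte, severe) without severe 3, and 0.58 (fatty acid, moderate), 0.074 (macrophage, moderate), 0.53 (oxidative phosphorylation, severe), 0.42 (adipocyte, severe) and 0.96 (macrophage, trend) without the 3 libraries low in myoglobin, where the 2 moderate results rest on moderate 2 alone. The cause was not tested. In all, 823 of the alternative list results kept direction and call, 213 kept direction and lost the call, and 9 reversed. For named genes 7057 results kept their call, or stayed uncalled with a change within the spread between replicates, whatever the sign. Another 163 stayed uncalled but moved by more than that spread, and 71 gained a call (46 of them without severe 2). The 54 lost calls all fell on the 3 trend genes and on LOC303448 between severe and moderate. These were the only named results called in the main fit, so most of the 7057 had no call to lose.

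Omitting 1 library at a time gave 0 to 1 genes in mild, 0 to 19 in moderate, 0 to 136 in severe, 0 to 33 in moderate against mild, 0 to 9 in severe against moderate, 0 to 180 in severe against mild, 0 to 221 in the trend and 0 to 51 for any difference. Lists ranged over 3 to 10 in mild, 15 to 21 in moderate, 11 to 18 in severe and 14 to 18 in the trend. Over omitted libraries, adjusted p ranged from 1e-08 to 0.45 for "oxidative phosphorylation, nuclear-encoded, severe vs control" and from 1.3e-07 to 0.69 for "adipocyte markers, severe vs control". Correlations of fold changes ranged from -0.03 (without mild 1) to 0.26 for mild with moderate, 0.07 to 0.31 for mild with severe and 0.41 to 0.78 for moderate with severe.

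Replicate numbers 1 to 3 of control, moderate and severe animals gave no clear sign of pairing. Of 9 same-number pairs 1 had a correlation of deviations over 0.1, with a median of 0.083 against -0.027 for different numbers. With 3 libraries per group the deviations from a group mean offset each other, so this check cannot exclude pairing. With the replicate block the 9 libraries gave 0 genes in moderate, severe and severe against moderate, and 0 without the block. The planned count tests were not run, because the table holds RPKM. At 2.11 to 3.01 M reads, genes with a few reads change in steps of single reads.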

Other observations

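The tests of list scores per animal, of fibre type and fat, of depth and of the Zfp genes were chosen only after the result was seen; the splits of the samples were set beforehand.

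11 genes known from blood vessels were picked here after their values were seen, so they are given singly and not as a tested group; the fixed endothelial list had a mean slope of -0.01 (adjusted p = 0.951). Per 10 °C of cooling the vessel transcription factors Sox18 (-0.74, SE 0.14), Elk3 (-0.35) and Meox2 (-0.41), the apelin receptor Aplnr (-0.97, SE 0.20), the gap junction protein Gja5 (-0.73, SE 0.14), Arhgef15 (-0.63), Myct1 (-0.65), Pcdh12 (-0.56) and Cd200 (-0.52) had adjusted p of 0.061 to 0.098. Aplnr read 8.89 ± 2.1 RPKM in controls and 1.82 ± 2.1 RPKM in severe animals (n = 3). Cldn5, a tight junction protein of the same cells, went the other way from 15.1 to 55.9 RPKM (0.76, adjusted p = 0.051), as did Adm (0.85, adjusted p = 0.051). None of the 11 passed as deposited, and after rescaling by the median of ratios Cldn5 and Adm did (adjusted p = 0.035 each). Each passed without severe 2, where 221 genes did, and none did without severe 3, where 0 genes did.

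Sat1 had a slope of 0.84 per 10 °C (adjusted p = 0.077) and Amd1, needed for polyamine synthesis, one of -0.41 (adjusted p = 0.061); neither passed, and no polyamine list was tested. The row named for the microRNA Mir133a had a slope of -0.94 (adjusted p = 0.093), from 9.34, 2.44 and 2.23 RPKM in controls to 0.0773, 0.0726 and 0.198 RPKM in severe animals. At the implied depths these severe values are too small for 1 read on a microRNA precursor, so what the Mir133a row measures is uncertain. Of 156 genes with Zfp symbols 118 had slopes below 0, as had 62.7% of all genes. The Zfp median was -0.09 against -0.03 for all genes, with a camera p of 0.0011 and p = 0.10 with an estimated correlation. As 9 of them past an adjusted p of 0.1 had prompted the look, 8 lower and Zfp36 higher (1.21, adjusted p = 0.084), the other 147 were tested alone, with a camera p of 0.012 and p = 0.17 with an estimated correlation. An earlier set of 150, which left out Zfp36 by choice and symbols of another form, had given a camera p of 0.00012 (0.066 with an estimated correlation), and 117 of its slopes lay below 0 as deposited, 108 after the median of ratios and 110 after quantile normalization. LOC257642 read 114, 127 and 113 RPKM in controls and 46.5 to 100 RPKM in the 9 cooled libraries, and LOC310926 133, 148 and 125 against 38.2 to 110 RPKM. Both loci were picked outside the naming rule, and neither passed the adjusted threshold over all genes in any comparison.

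The higher immediate early, glucocorticoid-responsive and atrophy genes at low temperature were weighed as 1 joint score of 73 genes, which had a slope of 0.54 per 10 °C (SE 0.16). Shares of fat and slow fibres as the whole cause would remove the slope, yet it was 0.52 (SE 0.14) with both scores as covariates, and depth or scaling would too, yet it was 0.54 (SE 0.15) on rescaled values with the implied reads as a covariate. Leaving out single libraries gave slopes of 0.45 to 0.64, but the 3 mild animals (4.36, 4.18 and 4.16) lay below the 3 controls (4.67, 4.74 and 4.47), so the score did not climb through each stage. Cooling and the time it took may be behind the trend, and this stays open: permuting the temperatures gave p of 0.043 for the glucocorticoid and atrophy lists, and for the hypoxia list outside this score, after adjustment over 29 lists, but 0.11 for the immediate early list. This test replaced a permutation of the joint score (p = 0.0096) after that was seen, as the 3 lists had been picked for their trend; time in the cold, time under anaesthesia and handling were not tested and cannot be separated from temperature.

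Low slow-twitch and high adipocyte genes in moderate 1, moderate 3 and severe 3 were weighed next; 9 of the 11 adipocyte markers also averaged at least 1 RPKM in controls, and Adipoq averaged 5.84 RPKM there against 105, 42.6 and 120 RPKM in moderate 1 to 3 and 1.22, 4.46 and 617 RPKM in severe 1 to 3. Fat that dilutes muscle RNA would lower fast and slow fibre genes alike, but fast minus slow scores differed by 3.36 (SE 1.35) between moderate and control animals. That contrast was judged by its SE alone with 3 animals per group, and it took in moderate 2 and left out severe 3. Fast-twitch scores were 11.88, 11.84 and 11.62 in moderate 1, moderate 3 and severe 3 against 11.62 to 11.79 in controls. Slow-twitch scores there were 3.05, 2.04 and 3.36 against 6.54 to 7.41, which argues against dilution as the whole cause. A different part of the muscle could have been sampled whatever the temperature, and this stays open, with a permutation p of 0.098 for the slow-twitch score among the 4 groups. That test replaced a bound of 50% on the variance within groups after the share was seen at 49.5%, too close to decide. Cooling itself stays open too, with a permutation p of 0.16 for the slow-twitch slope.

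Other splits of the samples were counted for each comparison. For pairs of groups the 10 splits of 6 libraries are too few for a share under 0.05. Real and highest other counts of genes were 0 and 0 in mild, moderate and severe against control and in moderate against mild, and 0 and 3 in severe against mild. A real count of 0 is reached by every split (10 of 10 in these comparisons), so these counts say nothing about chance. For lists they were 5 and 8 in mild (6 splits as large), 21 and 12 in moderate (1 split) and 13 and 15 in severe hypothermia (3 splits). Over 100 assignments of the 12 libraries, the real one included, 1 gave 3 or more genes with a trend (highest other 1), so no other assignment reached the real count. That share is the smallest that 100 assignments can give, and it was not adjusted over the counts tested. The count of 3 was also 0 without control 1, control 3 or severe 3, so chance was not excluded. For lists with a trend 11 of 100 gave 16 or more (highest other 20), so chance cannot be excluded for that count. For any difference the real count was 0, which 100 of 100 reach whatever the data. The highest other assignment there called 263 genes and put moderate 1, moderate 3 and severe 3 in 1 group, which points to a structure of the samples.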
